A study of Mus musculus with 59 samples.

How the data were processed

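Whole prefrontal cortex of 59 mice was sequenced after poly(A) selection with a stranded library kit, and 1 table of Ensembl genes by 59 libraries was used. The authors' processing notes name Salmon 0.11.2, R 3.6.0, DESeq2 1.19.11 and the genome build GRCm38, without saying which step each served. The deposited values are a normalised signal: estimated gene counts that the authors rounded and divided by 1 size factor per library. The size factor was read off each column as the step between its values, and every value between 1 and 1000 reads was a whole multiple of it in all 59 columns (100% within 0.01 read). Size factors ran from 0.827 to 1.129, the recovered reads from 24.99 to 32.87 M per library and the deposited sums from 28.49 to 31.12 M. The number of reads limits only the counting error; the gene filter behind the table, the annotation release and the litters are not stated. No column was left out. Symbols, positions, GC content and length came from GENCODE M21 (GRCm38), which held 18077 of the identifiers.

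Because the values were already scaled, the main test was limma-trend (limma 3.58.1, R 4.3.3) on log2 of the value plus 1, with 1 mean for each of the 12 groups of genotype, treatment and sex and 47 residual degrees of freedom. Genes with at least 10 in 4 or more libraries were tested (17891), with Benjamini-Hochberg adjustment and a threshold of 0.05 within each of 15 comparisons; tests were two-sided. Contrasts averaged groups with equal weights, interactions were differences of differences, and 14 comparisons of 2 groups gave the counts by stratum. Counts of libraries beside a gene are those of the first-named side that lay beyond the mean of the reference group of the same sex and of the same treatment or genotype. The 45 gene lists, of pathways, synaptic and receptor families and markers of cell types and neighbouring regions, were fixed before the data were examined. Each was tested with camera at a preset correlation of 0.01 and adjusted over the 45 lists. With an estimated correlation 0 lists were called in all 15 comparisons, where the preset called 7 to 22, so the p with an estimated correlation, adjusted likewise, stands beside each list. Members were also counted with p-values adjusted over the list alone, and a single pair of counts beside a list means that both agreed. Cell type lists measure marker levels in bulk tissue and assign no cells.

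The rule for named genes was fixed before the data were examined. In each main comparison it took the 8 largest increases and decreases among called genes at or above the median level. It also took up to 4 members with the smallest p of each list that was called or held a called gene, the 10 smallest p where fewer than 10 genes passed, and Naa15 everywhere. For females against males it took Xist, 4 Y-linked genes and up to 4 autosomal genes. Lower ranks were left out for length, a few other genes under the rule are not reported here, and genes named outside the rule are said to be so.

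Each library's profile was described by principal components of log2 values, by the share of 15 genes of the mitochondrial chromosome and by the slope of its log2 values, each less the gene's mean, on GC content and on log2 length. Alternatives fixed in advance were limma without the intensity trend, a robust variance prior, quantile normalisation, median centring, no filter, a mean of at least 100 and added constants of 0.5 and 5. Others were only the groups in a comparison, blocks by replicate number and by library number, 1 and 2 residual principal components, estimated list correlations, fry in place of camera, split vehicle libraries and leaving out each of the 59 libraries. Alternatives added after the data were seen were leaving out the 5 HT fluoxetine female libraries, and removing a natural-spline trend (5 degrees of freedom) on GC content and length from each library. Others were the GC and length slopes as covariates, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, which the authors' division by size factors had left recoverable. Replicate numbers did not pair the libraries (mean residual correlation 0.0104), and no pair of replicates was a duplicate.

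The comparison with shared vehicle libraries was judged beside 100 simulations of unchanged groups against the same controls and 20 random divisions of the vehicle libraries. In simulated data 200 genes were changed by 0.25, 0.5 or 1 on the log2 scale in the real layout. HT against WT under vehicle recovered 67.2%, 88.1% and 100% of these, with 7 false calls of 177. The interaction of genotype with fluoxetine recovered 37.3%, 80.6% and 95.5% with 9 of 151. Random regroupings of the libraries (closing section) called up to 2784 genes for it, so these rates leave out structure shared by libraries. Python 3.11.15 and matplotlib 3.10.9 drew the figures.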

Results

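Messenger RNA from the prefrontal cortex of C57BL/6J mice was sequenced at postnatal day 25 in 59 libraries. The mice were wild type (WT, 30 libraries) or heterozygous (HT, 29 libraries) for Naa15, which encodes the auxiliary subunit of NatA, the complex that acetylates the N-terminus of many proteins. Vehicle (19 libraries), the serotonin reuptake inhibitor fluoxetine (20 libraries) or the mood stabiliser lithium (20 libraries) reached the pups through their mothers' milk from postnatal day 3 to day 24. Genotype, treatment and sex (30 female and 29 male libraries) formed 12 groups of 5 libraries, except the HT vehicle males with 4. The labels do not give litters, so every p-value measures the spread between these samples. The deposited values, read counts that the authors divided by a size factor per library, stood for 24.99 to 32.87 M reads per library with a median of 29.1 M. Of the genes in the table, 17891 reached a normalised count of 10 in at least 4 libraries and were tested. Fold changes are given on the log2 scale with the SE of the fit, and a gene rose, fell or is called changed only where its adjusted p was under 0.05.

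The libraries formed separate sets along the first principal component, which held 14.4% of the variance. All 20 lithium libraries and the 5 HT fluoxetine female libraries lay between -31.6 and -14.9, and the other 34 libraries between -2.74 and 27.6. The same 25 libraries had a higher share of reads from the mitochondrial chromosome, 6.76% to 10.3% with a median of 7.98%, against 4.96% to 7.83% with a median of 5.84% in the other 34. Their values leaned towards genes of low GC content, with slopes of -0.263 to -0.0534 per 10 points of GC content against -0.0708 to 0.199. The HT fluoxetine female group therefore stood apart from the other fluoxetine groups in every comparison that includes it, and each such comparison was also run without these 5 libraries, a choice made after the data were seen.

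**Figure D1:**
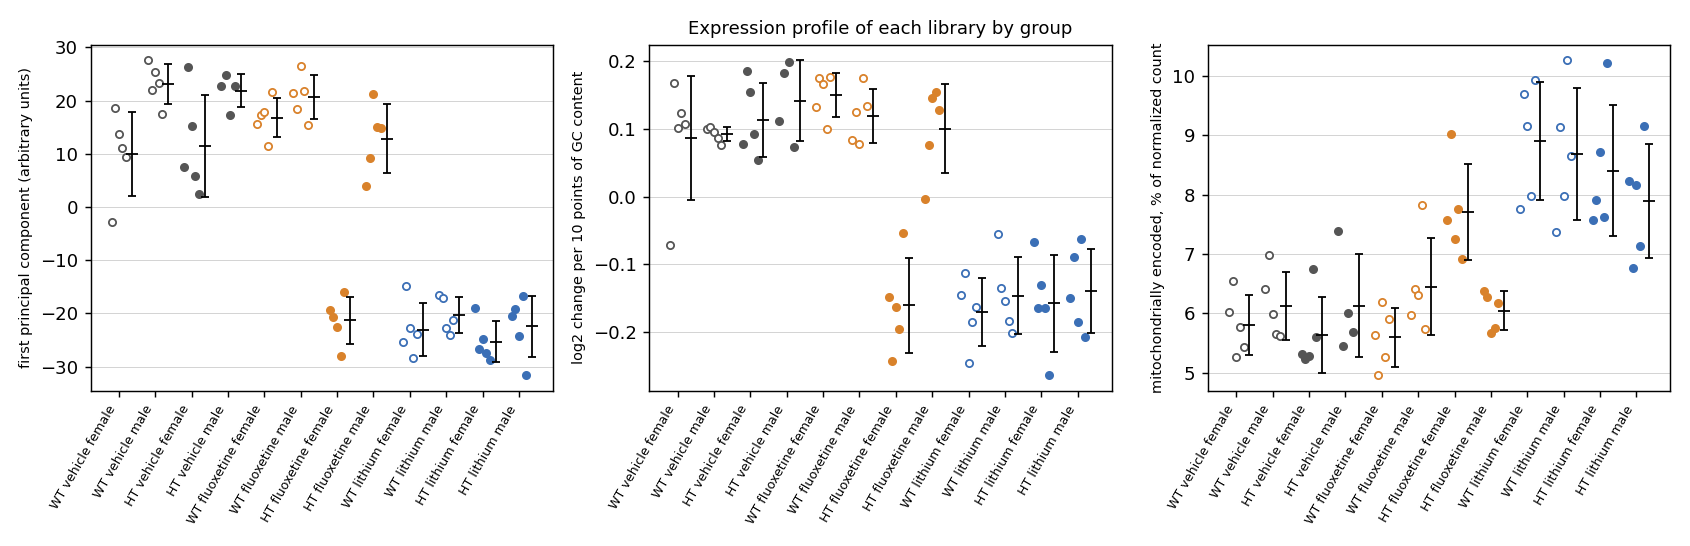
First principal component, slope of log2 values on GC content and share of mitochondrially encoded counts for each of the 59 libraries, with the mean and SD of each of the 12 groups (open circles WT, filled HT, grey vehicle, orange fluoxetine, blue lithium). The 5 HT fluoxetine female libraries lie with the 20 lithium libraries, at or below -14.9 on the first component.

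Naa15 (ENSMUSG00000063273, chromosome 3, 51415148 to 51476507, plus strand, GRCm38) was the targeted gene. Its normalised count was 1675 ± 182 (SD, n = 5) in WT vehicle females and 1633 ± 54.8 (SD, n = 5) in HT vehicle females. In the males it was 1592 ± 80.1 (SD, n = 5) and 1551 ± 49.1 (SD, n = 4). HT differed from WT by -0.03 ± 0.041 (adjusted p = 0.895, 6 of 9 libraries) under vehicle and by 0.02 ± 0.023 (adjusted p = 0.648, 14 of 29 libraries) over all treatments. Gene-level counts therefore did not separate the genotypes and do not check the labels. Naa15 rose under lithium by 0.12 ± 0.029 (18 of 20 libraries, adjusted p = 0.000363) and by 0.09 ± 0.028 against fluoxetine (adjusted p = 0.00886). The rise was 0.12 ± 0.040 in WT (adjusted p = 0.0116) and 0.12 ± 0.041 in HT (adjusted p = 0.0144). Under fluoxetine it differed by 0.03 ± 0.029 (adjusted p = 0.492) over both genotypes and by -0.05 ± 0.040 in WT (adjusted p = 0.722). It rose by 0.11 ± 0.041 in HT (adjusted p = 0.0366). These changes turned negative once the GC and length trend of each library was removed. They were then called in that direction at -0.13 for lithium, -0.11 and -0.16 in WT and HT and -0.11 against fluoxetine (adjusted p = 3.62e-06, 0.00526, 0.000192 and 0.000108), and not called at -0.04 for fluoxetine in HT (0.479). The call for fluoxetine in HT ended without the HT fluoxetine female libraries, which left HT males alone (adjusted p = 0.828). It also ended on leaving out any 1 of HT fluoxetine female replicates 2, 3 and 4 (0.0658, 0.0678, 0.0666), HT fluoxetine male replicate 1 (0.113), HT vehicle female replicates 2, 4 and 5 (0.0604, 0.0554, 0.053) and HT vehicle male replicates 2 and 4 (0.0679, 0.0666).

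HT was first compared with WT under vehicle, which asks what the genotype changes in animals given vehicle. The clearest difference was in Kif5c, a kinesin heavy chain that carries cargo along neuronal microtubules, with a normalised count of 26337 ± 1533 (SD, n = 5) in WT and 34635 ± 1919.6 (SD, n = 5) in HT females. Kif5c rose by 0.35 ± 0.032 (adjusted p = 1.58e-10, 9 of 9 libraries), where the libraries counted are the HT libraries above the WT mean of their sex. Kif5b, the ubiquitous member of the same kinesin family, rose by 0.23 ± 0.046 (adjusted p = 0.0112, 8 of 9 libraries). Hist1h1c, a linker histone, rose by 0.54 ± 0.12 (adjusted p = 0.0313, 9 of 9 libraries). Pcdhb5, a clustered protocadherin of neuronal cell recognition, fell by 0.43 ± 0.068 (adjusted p = 0.000157, 9 of 9 libraries). Gm14295 and Gm14296, zinc finger genes of a cluster on chromosome 2, fell by 0.35 and 0.33 (adjusted p = 0.0112 and 0.000599, 9 of 9 libraries).

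Genes named here only after their values were seen, because they lie below the level that the naming rule required, include Gm5784, which fell by 0.96 ± 0.14 (adjusted p = 4.48e-05, 9 of 9 libraries). Another was 2410018L13Rik, which fell by 0.70 ± 0.10 (adjusted p = 1.79e-05, 9 of 9 libraries). Gm14419 and Gm2004 of the chromosome 2 cluster fell by 0.84 and 0.98 (adjusted p = 1.79e-05 and 5.58e-05, 9 of 9 libraries). Reads of this zinc finger cluster, of Gm5784 and of the protocadherins can come from near-identical copies, so the member that changed is uncertain. Kif5c lies on chromosome 2, 49619298 to 49774778, plus strand, Gm14296 also on chromosome 2, Kif5b and Pcdhb5 on chromosome 18, Hist1h1c on chromosome 13 and Gm5784 on chromosome 12. None of these is on chromosome 3, which holds Naa15.

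Over all genes, 5 rose and 14 fell in HT vehicle animals (9 HT against 10 WT libraries). Of 31 histone genes, 1 rose and 0 fell, and 6 and 0 over the list alone. Their median was 0.11 (camera adjusted p = 7.19e-06, p = 0.318 with an estimated correlation). H1f0, a linker histone of resting cells, stood at 0.17 ± 0.042 (adjusted p = 0.105, 8 of 9 libraries). By sex, 1 gene rose and 2 fell in females and 6 and 5 in males. Kif5b lost its call without HT vehicle male replicate 3 (adjusted p = 0.0557) and Gm14295 without HT vehicle male replicate 2 (0.0781). Hist1h1c lost its call without any 1 of HT vehicle female replicates 1 and 3 (0.0519, 0.0688), HT vehicle male replicates 1 and 3 (0.0762, 0.121), WT vehicle female replicate 3 (0.088) and WT vehicle male replicates 1 and 3 (0.0723, 0.0587). Gm14295 and Gm14296 lost theirs at -0.32 and -0.28 with the GC and length trend removed (0.0673 and 0.0681). The 19 calls became 12 without HT vehicle female replicate 5, 11, 10 and 29 without HT vehicle male replicates 2, 3 and 4, and 11 without WT vehicle male replicate 5. They were 6 in a fit of these groups alone, 7 among genes with a mean of at least 100, 29 with the GC and length slopes as covariates, 53 and 133 with 1 and 2 residual components, and 30 with DESeq2.

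HT was next compared with WT over all treatments (29 against 30 libraries), which asks what the genotype changes whatever the treatment. Kif5c and Kif5b again rose, by 0.33 ± 0.018 and 0.28 ± 0.026 (adjusted p = 2.31e-19 and 4.43e-11, 29 and 28 of 29 libraries). Histone genes rose, Hist1h1c by 0.56 ± 0.066 (29 of 29 libraries), Hist1h1e by 0.61 ± 0.12 (26 of 29), H1f0 by 0.19 ± 0.024 (26 of 29) and the replacement histone gene H3f3a by 0.12 ± 0.022 (22 of 29; adjusted p 2.87e-08 to 0.000277). After poly(A) selection, a change in histone polyadenylation stays open. Pcdha12, a clustered protocadherin, fell by 0.43 ± 0.047 (adjusted p = 2.98e-09, 29 of 29 libraries). The imprinted neuronatin gene Nnat rose by 0.50 ± 0.11 (adjusted p = 0.00147, 25 of 29 libraries). Peg10, an imprinted retrotransposon-derived gene, rose by 0.26 ± 0.062 (adjusted p = 0.00226, 25 of 29 libraries). Lars2, the mitochondrial leucyl-tRNA synthetase, Glra2, a glycine receptor subunit, and Zcchc12 rose by 0.43 ± 0.13, 0.32 ± 0.093 and 0.31 ± 0.076 (adjusted p 0.00346 to 0.0215, 21 to 25 of 29 libraries). Besides Pcdha12, the largest decreases at or above the median level were those of Gm42047, 4930447C04Rik, Gm43305 and the collagen gene Col1a1, which fell by 0.49, 0.34, 0.34 and 0.32 (adjusted p 0.000186 to 0.0173, 22 to 26 of 29 libraries).

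By fixed gene lists, of 31 histone genes 12 rose and 0 fell, and 16 and 0 over the list alone (median 0.12, camera adjusted p = 5.49e-08, p = 0.109 with an estimated correlation). The list, matched by name, holds the non-histones H13 and H19. Of 55 clustered protocadherins 2 rose and 16 fell, and 3 and 18 over the list alone (median -0.08, camera adjusted p = 0.000233, p = 0.517 with an estimated correlation). Pcdhb5 stood at -0.31 ± 0.039 and Pcdhga2 at -0.33 ± 0.057 (adjusted p = 1.51e-07 and 4.66e-05, 26 of 29 libraries each). Without the HT fluoxetine female libraries the histone call stood (camera adjusted p = 6.84e-12) and the protocadherin call ended (0.113). Of 40 genes of postsynaptic scaffolds and adhesion 0 rose and 19 fell, and 0 and 27 over the list alone (median -0.07, camera adjusted p = 1.24e-10, p = 0.185 with an estimated correlation). Nlgn3, a neuroligin, fell by 0.08, Nrxn2, a neurexin, by 0.11 and Shank1, a scaffold of excitatory synapses, by 0.14 (adjusted p 6.5e-07 to 3.45e-05). Of 36 genes of presynaptic release 0 rose and 14 fell, and 0 and 20 over the list alone. Their median was -0.06 (camera adjusted p = 5.87e-07, p = 0.516 with an estimated correlation). Of 82 cytosolic ribosomal protein genes 24 rose and 2 fell, and 28 and 2 over the list alone (median 0.05, camera adjusted p = 5.36e-07, p = 0.675 with an estimated correlation). Rps4l, an expressed copy of a ribosomal protein gene whose reads it shares, fell by 0.57 ± 0.068 (adjusted p = 4.4e-08, 28 of 29 libraries). Of 17 markers of dividing or immature cells 4 rose and 1 fell, and 13 and 1 over the list alone. Their median was 0.26 (camera adjusted p = 8.08e-05, p = 0.41 with an estimated correlation). Cd24a, a surface protein of immature neurons, rose by 0.26 ± 0.059 (adjusted p = 0.00182). Of 15 markers of the olfactory bulb and rostral stream 0 rose and 0 fell (median 0.45, camera adjusted p = 0.00214, p = 0.681 with an estimated correlation). Htr2a, a serotonin receptor, fell by 0.16 ± 0.048 (adjusted p = 0.0213, 21 of 29 libraries). Ctnnb1, which encodes beta-catenin, rose by 0.09 ± 0.016 (adjusted p = 0.000143, 29 of 29 libraries).

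In all, 921 genes rose and 1716 fell, with a median size of 0.10 among the called genes. The synaptic and ribosomal lists moved in the direction of the 25 libraries described above, 5 of which are HT fluoxetine females with no WT counterpart. Without those 5 libraries 197 genes rose and 333 fell, and 440 of the 530 were also called with them, in the same direction. Of the postsynaptic, presynaptic and ribosomal lists 0, 1 and 1 genes then fell and 0 rose, with medians of -0.03, -0.02 and 0.03. Glra2, Lars2 and Gm43305 lost their calls at similar folds of 0.30, 0.37 and -0.29 (adjusted p 0.0968 to 0.15). Nlgn3, Nrxn2, Shank1, Col1a1 and H3f3a lost theirs at smaller folds of -0.03, -0.01, -0.07, -0.22 and 0.07 (adjusted p 0.104 to 0.797). Kif5c, Kif5b, Hist1h1c, H1f0, Pcdha12, Pcdhb5, Nnat and Ctnnb1 kept theirs (adjusted p up to 0.00362). With both slopes as covariates Gm43305 lost its call at -0.21 (adjusted p = 0.204). Named after their values were seen, Gm5784 and 2410018L13Rik fell by 1.18 and 0.82 (both adjusted p = 2.1e-16, 29 of 29 libraries each). Trim71, a repressor of differentiation in early development, was picked likewise and rose by 0.57 ± 0.067 (adjusted p = 2.94e-08, 27 of 29 libraries).

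Fluoxetine was compared with vehicle over both genotypes (20 against 19 libraries), which asks what fluoxetine in the milk changes in the young cortex. Several genes induced by glucocorticoids rose. Fkbp5, a chaperone of the glucocorticoid receptor, rose by 0.55 ± 0.062 (adjusted p = 1.42e-08, 20 of 20 libraries), from a normalised count of 798 ± 48.1 (SD, n = 5) to 1404 ± 294 (SD, n = 5) in WT males. Zbtb16, Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, and Sult1a1, a sulfotransferase, rose by 0.55 ± 0.080, 0.34 ± 0.063 and 0.59 ± 0.10 (adjusted p 2.35e-06 to 7.24e-05, 19 to 20 of 20 libraries). Trir, a telomerase RNA-interacting RNase, rose by 0.36 ± 0.058 (adjusted p = 1.07e-05, 19 of 20 libraries). Several genes switched on by neuronal activity fell. Arc, an activity-regulated synaptic protein, fell by 0.89 ± 0.18 (adjusted p = 0.000196, 18 of 20 libraries). In WT males its count went from 6184 ± 789 (SD, n = 5) to 2569 ± 347 (SD, n = 5). The transcription factor genes Fos, Nr4a1 and Junb, the kinase gene Sik1 and the phosphatase gene Dusp1 fell by 0.70, 0.67, 0.56, 0.60 and 0.58 (adjusted p 2.57e-07 to 0.000326, 17 to 20 of 20 libraries).

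Of 20 glucocorticoid response genes 10 rose and 3 fell, and 13 and 3 over the list alone (median 0.11, camera adjusted p = 0.000145, p = 0.319 with an estimated correlation). Of 32 immediate early genes 2 rose and 21 fell, and 3 and 23 over the list alone. Their median was -0.31 (camera adjusted p = 8.65e-09, p = 0.368 with an estimated correlation). Of 25 genes of cholesterol synthesis 0 rose and 17 fell, and 0 and 18 over the list alone (median -0.17, camera adjusted p = 1.28e-13, p = 0.186 with an estimated correlation). Insig1, the sterol-dependent brake on the pathway, fell by 0.28 ± 0.030 (adjusted p = 8.44e-09, 20 of 20 libraries). Srebf2, a transcription factor of sterol synthesis, fell by 0.17 (adjusted p = 2.99e-08) and stood at -0.09 without the HT fluoxetine females. Of 23 genes of the unfolded protein response 10 rose and 1 fell, and 10 and 2 over the list alone. Their median was 0.11 (camera adjusted p = 9.94e-05, p = 0.368 with an estimated correlation). Xbp1, the main transcription factor of this response, stood at 0.26 ± 0.035, the co-chaperone gene Dnajc3 at 0.18 ± 0.028 and Hspa5, the chaperone BiP, at 0.26 ± 0.052 (adjusted p 4.91e-07 to 0.000257, 20 of 20 libraries; 0.0934 for Hspa5 with both slopes as covariates). Of 23 Wnt and beta-catenin targets 0 rose and 6 fell, and 0 and 7 over the list alone. Their median was -0.08 (camera adjusted p = 0.00136, p = 0.186 with an estimated correlation). Nkd1, a feedback inhibitor of Wnt signalling, fell by 0.28 (adjusted p = 2.57e-07). These 5 lists were called without the HT fluoxetine female libraries too (camera adjusted p 1.79e-23 for cholesterol synthesis to 0.0439 for Wnt targets). The median of the Wnt targets, of which 0 rose and 2 fell, was then -0.03. By group it was -0.005 in WT females and WT males, -0.21 in HT females and -0.13 in HT males. Hif3a, a hypoxia-inducible factor subunit, and the kinase gene Map3k6, named after their values were seen, rose by 0.92 ± 0.10 and 0.81 ± 0.087 (adjusted p = 1.42e-08 and 8.44e-09, 20 of 20 libraries each).

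**Figure D2:**
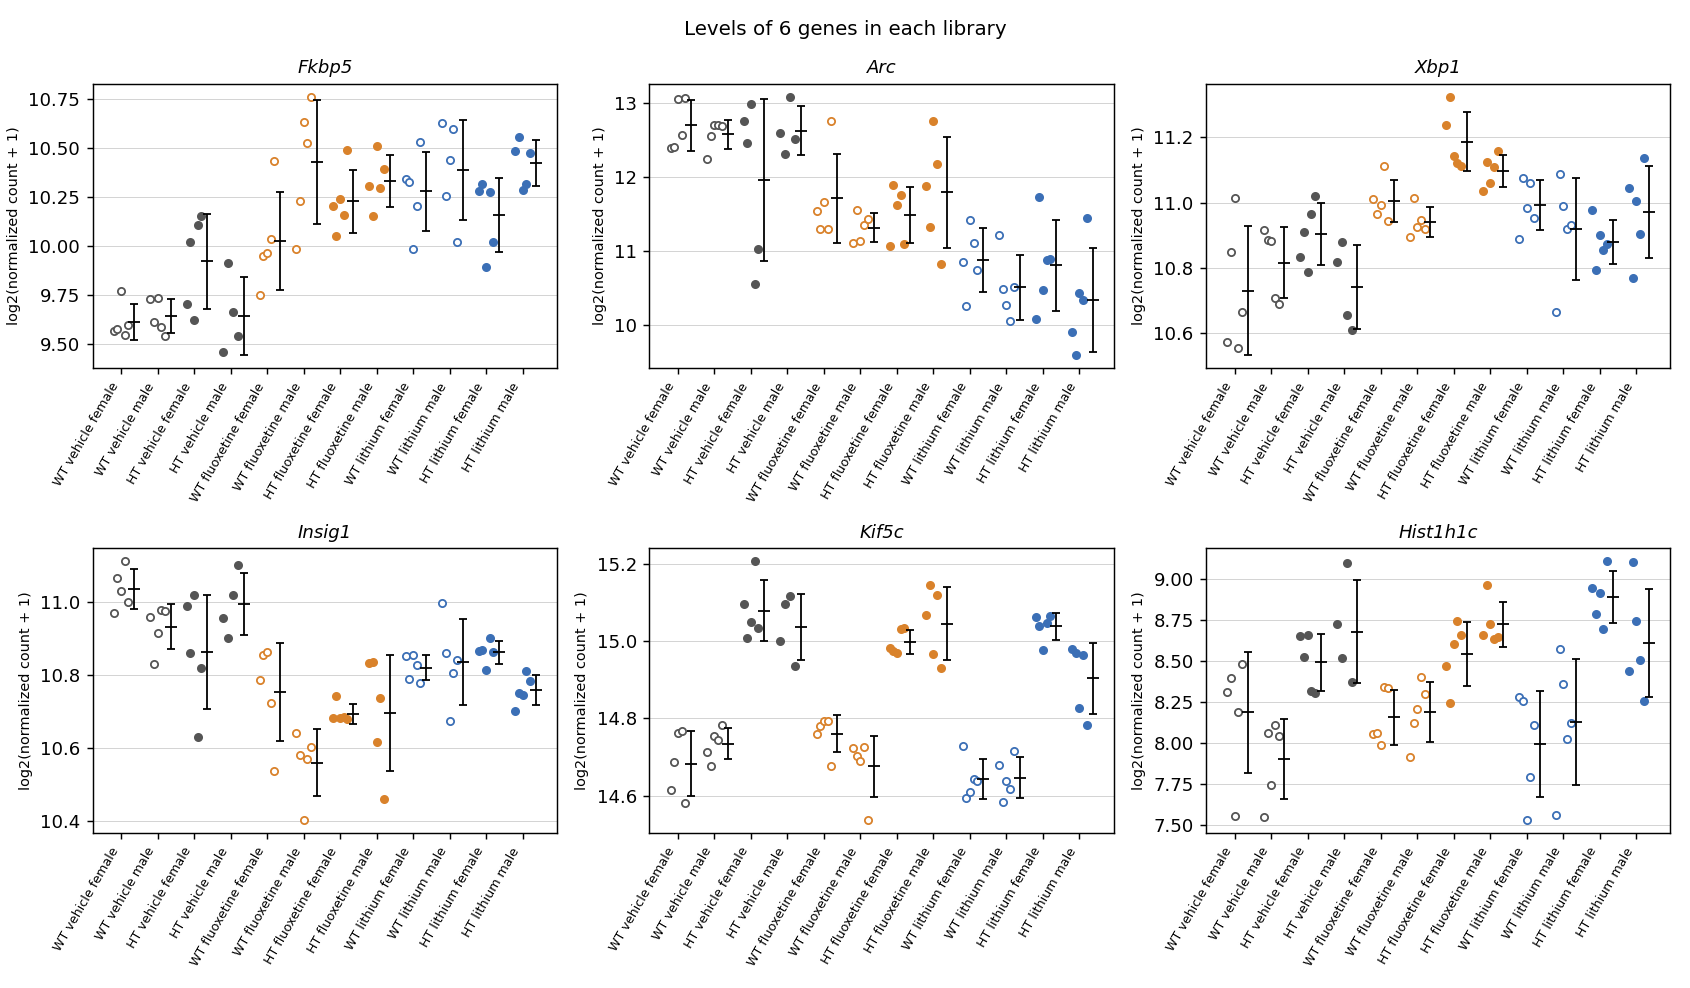
Normalised counts of Fkbp5, Arc, Xbp1, Insig1, Kif5c and Hist1h1c in each library on the log2 scale, with the mean and SD of each of the 12 groups (open circles WT, filled HT, grey vehicle, orange fluoxetine, blue lithium). The means of Kif5c and Hist1h1c are higher in each HT group than in the WT group of the same treatment and sex, and those of Fkbp5 higher and of Arc lower in each drug group than in the vehicle group of the same genotype and sex.

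Respiratory and ribosomal medians were highest in HT females. Of 80 nuclear genes of oxidative phosphorylation 45 rose and 1 fell, and 52 and 1 over the list alone (median 0.10, camera adjusted p = 1.53e-14, p = 0.368 with an estimated correlation). Of 82 cytosolic ribosomal protein genes 43 rose and 2 fell, and 45 and 2 over the list alone. Their median was 0.09 (camera adjusted p = 1.26e-13, p = 0.368 with an estimated correlation). Without the 5 HT fluoxetine female libraries 4 and 1 of these rose and 0 fell, at smaller medians of 0.03 and 0.04 (camera adjusted p = 4.61e-06 and 9.38e-07). By group the medians were 0.29 and 0.24 in HT females, 0.04 and 0.04 in HT males, 0.03 and -0.003 in WT females and 0.02 and 0.08 in WT males. Ndufb2, a subunit of complex I, and Cox5a, a subunit of cytochrome c oxidase, rose by 0.19 ± 0.021 and 0.24 ± 0.034 (adjusted p = 1.42e-08 and 1.2e-06, 19 to 20 of 20 libraries), and stood at 0.09 and 0.19 without the 5. Of 40 genes of postsynaptic scaffolds and adhesion 2 rose and 16 fell, and 2 and 17 over the list alone. Their median was -0.06 (camera adjusted p = 5.71e-05, p = 0.368 with an estimated correlation). Of 13 mitochondrially encoded genes 3 rose and 0 fell (median 0.11, camera adjusted p = 0.029, p = 0.574 with an estimated correlation). Both of these calls ended without the 5 libraries, where 1 and 0 rose and 0 fell (camera adjusted p = 0.913 and 0.919). mt-Nd3, a mitochondrially encoded subunit of complex I, stood at 0.43 ± 0.14 (adjusted p = 0.0236; 0.25, adjusted p = 0.609, without these libraries and 0.0583 without HT vehicle male replicate 2). mt-Atp6, a subunit of ATP synthase, was at 0.26 ± 0.076, which turned to -0.14 without them. In all 1739 genes rose and 1840 fell, and 216 and 156 without the 5 libraries, of which 335 were shared in direction with the full set.

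In WT mice alone, 113 genes rose under fluoxetine and 69 fell (10 against 10 libraries), with 20 and 5 in females and 15 and 8 in males. Of the immediate early genes 1 rose and 10 fell, and 1 and 21 over the list alone (median -0.42, camera adjusted p = 9.02e-18, p = 0.0851 with an estimated correlation). Of the cholesterol genes 0 rose and 5 fell, and 0 and 15 over the list alone. Their median was -0.11 (camera adjusted p = 4.36e-17, p = 0.0851 with an estimated correlation). Of the unfolded protein response 2 rose and 0 fell, and 12 and 0 over the list alone (median 0.10, camera adjusted p = 8.36e-06, p = 0.303 with an estimated correlation). Of the glucocorticoid response 5 rose and 2 fell, and 9 and 3 over the list alone. Their median was 0.10 (camera adjusted p = 3.05e-05, p = 0.157 with an estimated correlation). The 182 calls became 121 and 120 without WT fluoxetine female replicates 3 and 5, 96 without WT fluoxetine male replicate 4, 108 and 294 without WT vehicle female replicates 1 and 2, and 114 and 97 without WT vehicle male replicates 4 and 5. They were 380 and 692 with 1 and 2 residual components. In HT mice 2656 rose and 2923 fell, with 3376 and 3480 in females and 17 and 12 in males. Without the HT fluoxetine females the HT comparison was of males alone, and 15 rose and 11 fell.

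Lithium was compared with vehicle over both genotypes (20 against 19 libraries), which asks what lithium in the milk changes. Activity-regulated genes had the largest decreases among genes at or above the median level. Arc fell by 1.84 ± 0.18 (adjusted p = 2.24e-13, 20 of 20 libraries), to 1511 ± 514 (SD, n = 5) in WT males. Fos, Sik1, Junb, Klf10, Egr1 and Jun fell by 1.22, 1.08, 0.997, 0.97, 0.91 and 0.46 (adjusted p 1.18e-17 to 1.48e-10, 20 of 20 libraries). Of 32 immediate early genes 4 rose and 24 fell (median -0.56, camera adjusted p = 1.08e-05, p = 0.359 with an estimated correlation). At or above the median level mt-Atp6, mt-Nd3 and mt-Co2 rose most. mt-Atp6 rose by 1.61 ± 0.076 (adjusted p = 1.87e-24, 20 of 20 libraries), from 17319.8 ± 3509 (SD, n = 5) to 53152 ± 7205 (SD, n = 5) in WT females. mt-Nd3 and mt-Co2, a subunit of cytochrome c oxidase, rose by 1.18 ± 0.14 and 1.08 ± 0.15 (adjusted p = 2.03e-10 and 2.01e-08). Lars2 rose by 1.04 ± 0.16 (adjusted p = 1.82e-07, 19 of 20 libraries).

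Wnt, inositol and clock genes changed, as did 11287 of all 17891 genes. Of 23 Wnt and beta-catenin targets 0 rose and 17 fell (median -0.17, camera adjusted p = 0.00148, p = 0.249 with an estimated correlation). Nkd1 fell by 0.59 ± 0.037 (adjusted p = 3.95e-20, 20 of 20 libraries). Lef1, a nuclear partner of beta-catenin, and Axin2, a scaffold of its degradation complex, fell by 0.84 and 0.32 (20 of 20 libraries). Of 33 genes of inositol and phosphoinositide metabolism 7 rose and 16 fell, and 7 and 17 over the list alone. Their median was -0.12 (camera adjusted p = 0.0211, p = 0.359 with an estimated correlation). Itpkb, an inositol trisphosphate kinase, fell by 0.45, Cds2, which makes the CDP-diacylglycerol needed for phosphatidylinositol, fell by 0.22, and Impa1, the inositol monophosphatase that lithium inhibits, rose by 0.22 ± 0.017 (adjusted p 2.54e-17 to 1.14e-15, 20 of 20 libraries). Impa1 stood at 0.02 (adjusted p = 0.561) once the GC and length trend was removed. Of 20 circadian clock genes 2 rose and 11 fell (median -0.21, camera adjusted p = 0.0151, p = 0.359 with an estimated correlation). The repressor genes were lower, Nr1d1 at -0.66 ± 0.034, Cry2 at -0.32 ± 0.022 and Per1 at -0.71 ± 0.058 (20 of 20 libraries). Of 20 glucocorticoid response genes 12 rose and 5 fell. Their median was 0.14 (camera adjusted p = 0.207, p = 0.744 with an estimated correlation). Fkbp5 was at 0.61 ± 0.062 and Sult1a1 at 0.93 ± 0.10 (adjusted p = 1.56e-12 and 3.75e-12).

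Synaptic genes fell. Of 40 genes of postsynaptic scaffolds and adhesion 3 rose and 29 fell, and 3 and 31 over the list alone (median -0.27, camera adjusted p = 1.97e-08, p = 0.311 with an estimated correlation). Of 36 genes of presynaptic release 2 rose and 27 fell (median -0.23, camera adjusted p = 1.08e-05, p = 0.362 with an estimated correlation). Nrxn2 fell by 0.48, Nlgn3 by 0.30, Syn1, which encodes synapsin of the vesicle pool, by 0.37, and the NMDA receptor subunit genes Grin2d and Grin1 by 0.64 and 0.39 (adjusted p 8.62e-26 to 6.82e-19, 20 of 20 libraries). Ncan, which encodes the matrix protein neurocan, fell by 0.48 ± 0.017 (adjusted p = 1.35e-28, 20 of 20 libraries). Pvalb, the calcium buffer of fast-spiking interneurons, rose by 0.78 ± 0.069 (adjusted p = 1.64e-14, 20 of 20 libraries). Of 21 endothelial and mural markers 2 rose and 14 fell (median -0.46, camera adjusted p = 0.00121, p = 0.491 with an estimated correlation). The pericyte genes were lower, Pdgfrb at -0.52 ± 0.037 and Cspg4 at -0.52 ± 0.039, as was the endothelial cadherin gene Cdh5 at -0.59 ± 0.046 (20 of 20 libraries). Of 80 nuclear genes of oxidative phosphorylation 61 rose and 11 fell, and 61 and 12 over the list alone. Their median was 0.30 (camera adjusted p = 1.53e-12, p = 0.359 with an estimated correlation). Of 82 cytosolic ribosomal protein genes 60 rose and 8 fell, and 61 and 8 over the list alone (median 0.28, camera adjusted p = 3.99e-12, p = 0.359 with an estimated correlation). Of 13 mitochondrially encoded genes 12 rose and 0 fell (median 0.50, camera adjusted p = 0.000203, p = 0.359 with an estimated correlation). Atp5mpl of the ATP synthase and Rpl22l1 of the large ribosomal subunit rose by 0.58 ± 0.022 and 0.71 ± 0.033 (20 of 20 libraries). Gm28438, Gm15387 and Gm29216, copies of mitochondrial genes, and Gm4724 rose by 0.90, 0.83, 0.80 and 0.90. They share reads with parent genes, so the folds of both, and perhaps of mt-Atp6 throughout, are uncertain.

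In all, 5852 genes rose under lithium and 5435 fell, with a median size of 0.24 among them; 4764 rose and 4703 fell in WT and 4603 and 4451 in HT. Every lithium library lay among those with more mitochondrial reads and a lean towards low GC content, and the ribosomal, respiratory, mitochondrial and synaptic groups moved with that difference. With the GC and length trend of each library removed, 9209 genes were called and the list calls for the mitochondrially encoded genes and Wnt targets ended (camera adjusted p = 0.295 and 0.0814), at medians of 0.06 and -0.10. Of their members 5 rose and 2 fell, and 1 and 9. mt-Atp6, mt-Co2 and mt-Nd3 were still called at 1.16, 0.71 and 0.43, and Lef1, Nkd1 and Axin2 at -0.79, -0.39 and -0.17. The list calls for immediate early genes, circadian genes and both synaptic lists stood (0.000234, 0.00165, 0.00137 and 0.00566). The medians of both synaptic lists were -0.10 and -0.11, and those of the vascular and oxidative phosphorylation lists -0.26 and 0.15. Synaptic folds were smaller, with Nrxn2, Nlgn3, Syn1, Grin2d, Grin1 and Ncan at -0.16, -0.15, -0.09, -0.22, -0.10 and -0.20. Pdgfrb, Cspg4, Per1, Jun, Atp5mpl and Rpl22l1 were at -0.26, -0.19, -0.38, -0.24, 0.34 and 0.35, and Gm28438, Gm4724 and Gm29216 at 0.17, 0.57 and 0.39. With both slopes as covariates 1603 genes were called. Of the 46 genes named for lithium the calls of 14 stood: mt-Atp6, Lars2, Gm15387, Fkbp5, Nkd1, Lef1, Impa1, Nr1d1, Nlgn3, Nrxn2, Syn1, Ncan, Cdh5 and Atp5mpl. Those of the other 32 ended (adjusted p 0.0561 to 0.988). Among these, Arc, Fos, Junb, Klf10, Nr4a1, Egr1, Sult1a1, Hif3a, mt-Co2, Axin2, Itpkb, Pdgfrb, Pvalb and Naa38 were within 1.5 times of their folds, with Arc at -1.91 and Fos at -1.20. Smaller folds were those of Sik1, Jun, Per1, Cds2, Cry2, Maoa, Grin2d, Grin1, Cspg4, Rpl22l1, Gm4724 and Naa20, at -0.71, -0.10, -0.20, -0.08, -0.15, 0.04, -0.33, -0.03, -0.11, 0.18, 0.38 and 0.16. Those of mt-Nd3, Gm28438, Gm29216, Htr2a and Naa15 turned negative and that of Htr6 positive.

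Serotonin genes were examined because fluoxetine acts on serotonin uptake. Of 18 serotonin receptor and metabolism genes under fluoxetine 1 rose and 0 fell (median 0.03, camera adjusted p = 0.552, p = 0.669 with an estimated correlation). Under lithium 6 rose and 3 fell (median 0.10, camera adjusted p = 0.713, p = 0.872 with an estimated correlation). Htr2a rose by 0.19 ± 0.059 under fluoxetine (adjusted p = 0.0147) and 0.21 ± 0.059 under lithium (adjusted p = 0.0019). With the GC and length trend removed these were 0.18 and 0.10 (adjusted p 0.073 and 0.214). Without the HT fluoxetine females the first was 0.16 (0.305). Under lithium Maoa, which degrades serotonin, rose by 0.22 ± 0.023 (adjusted p = 2.75e-12). Htr6, another receptor, fell by 0.43 ± 0.056 (adjusted p = 2.46e-09, 20 of 20 libraries for both). They stood at 0.06 and -0.15 (adjusted p = 0.04 and 0.00515) with that trend removed. Of 13 NatA and other N-terminal acetyltransferase genes under lithium 8 rose and 2 fell (median 0.12, camera adjusted p = 0.0931, p = 0.359 with an estimated correlation). Naa20 was at 0.31 ± 0.018 and Naa38 at 0.36 ± 0.040, and Naa20 stood at 0.02 (adjusted p = 0.367) once the GC and length trend was removed, where 3 of the 13 rose and 5 fell.

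**Figure D3:**
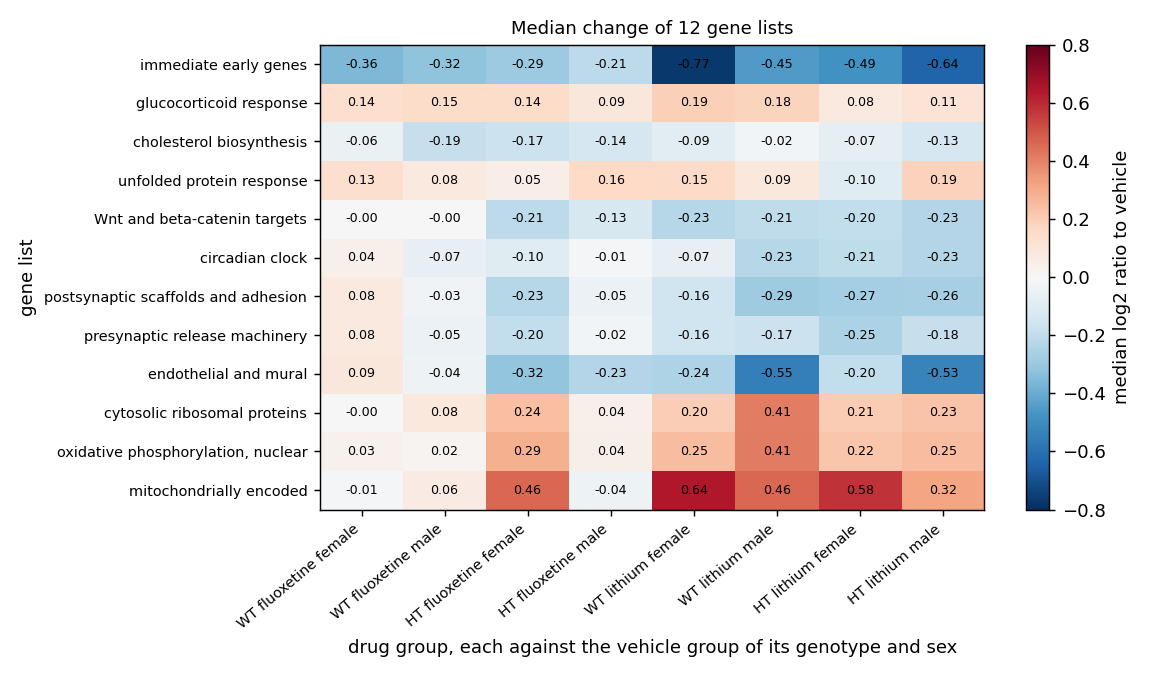
Median log2 ratio to the vehicle group of the same genotype and sex for 12 gene lists (vertical axis) in the 8 drug groups (horizontal axis), with red for higher and blue for lower. Immediate early genes are lower (-0.77 to -0.21) and glucocorticoid response genes higher (0.08 to 0.19) in all 8 groups, and mitochondrially encoded genes are at 0.32 to 0.64 in the lithium and HT fluoxetine female groups.

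Lithium was then compared with fluoxetine (20 against 20 libraries), which asks where the drugs differ. mt-Atp6 and mt-Co2 were higher under lithium by 1.35 ± 0.074 and 0.995 ± 0.15 (adjusted p = 1.66e-20 and 1.69e-07, 19 of 20 libraries). Gm21887, sharing reads with related genes, was at -1.22 ± 0.21 (adjusted p = 2.23e-06, 17 of 20 libraries). Arc was at -0.95 ± 0.17 (adjusted p = 5.96e-06, 19 of 20 libraries). The immediate early genes Jun, Egr3 and Egr4 stood at -0.34 ± 0.035, -0.44 ± 0.047 and -0.63 ± 0.070 (20 of 20 libraries). Of 32 immediate early genes 3 were higher and 20 lower. Their median was -0.33 (camera adjusted p = 0.003, p = 0.554 with an estimated correlation). Of the postsynaptic genes 1 was higher and 27 lower. Their median was -0.19 (camera adjusted p = 3.8e-09, p = 0.363 with an estimated correlation). Of the oxidative phosphorylation genes 55 were higher and 7 lower, and 55 and 8 over the list alone (median 0.19, camera adjusted p = 2.24e-11, p = 0.427 with an estimated correlation). Of the circadian genes 1 was higher and 11 lower, and 1 and 12 over the list alone (median -0.13, camera adjusted p = 0.00782, p = 0.382 with an estimated correlation), and Nr1d1 was at -0.42 ± 0.033. Hspa1a, the stress-induced chaperone, stood at -0.53 ± 0.050 and the heat shock protein gene Hsp90ab1 at -0.24 ± 0.025. Itpkb was at -0.33 ± 0.032. With the GC and length trend removed Jun, Egr3, Egr4 and Hspa1a were at -0.19, -0.29, -0.29 and -0.32, and the immediate early call ended (camera adjusted p = 0.0645, median -0.21). With both slopes as covariates the calls of mt-Atp6, Egr3 and Nr1d1 stood and the other 9 of 12 ended (adjusted p 0.0956 to 0.914). Arc, mt-Co2 and Itpkb were then at -1.002, 0.79 and -0.24, Jun, Egr4, Hspa1a, Hsp90ab1 and Gm21887 at -0.07, -0.25, -0.03, -0.09 and -0.35, and Naa15 at -0.13. In all 4950 genes were higher and 4688 lower under lithium. By stratum 7295 genes were called in WT females, 7525 in WT males and 5636 in HT males, but 10 in HT females, whose fluoxetine libraries lay with the lithium libraries.

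Both drugs shared the same vehicle libraries, which by itself makes their changes correlate. Across the 17891 genes, which are not independent replicates, the fold changes of fluoxetine and lithium had a Pearson r of 0.630 over both genotypes, where 100 simulations of unchanged groups gave 0.514. In WT, r was 0.263 and simulated 0.497, and the covariance was 0.0158 against 0.0130 simulated. With separate sets of vehicle libraries, r was 0.0271. In HT, r was 0.763 against 0.527, and 0.462 with separate sets. Without the HT females, r was 0.322 against 0.517. Of the 113 genes that fluoxetine raised in WT, 62 rose and 20 fell under lithium. Of the 69 lowered, 50 fell and 1 rose, and part of this overlap can come from the shared vehicle libraries. Fkbp5, Sult1a1, Hif3a, Arc, Fos, Nr4a1, Sik1 and Nkd1 changed in the same direction under both drugs. Hif3a, chosen after its values were seen, rose by 1.05 ± 0.10 (adjusted p = 5.98e-13, 20 of 20 libraries) under lithium. Nr4a1 fell by 0.97 ± 0.10 (adjusted p = 7.98e-12, 19 of 20 libraries).

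Whether the genotype alters the response to fluoxetine was tested as an interaction (HT response minus WT response). Among the largest decreases, Col1a1, a fibrillar collagen, was at -0.85 ± 0.22, Hspg2, perlecan of basement membranes, at -0.62 ± 0.10, Acta2, smooth muscle actin, at -0.62 ± 0.15, and Vwf, the endothelial von Willebrand factor, at -0.60 ± 0.10 (adjusted p 8.33e-06 to 0.00384). mt-Atp6 had a more positive response at 0.86 ± 0.15 (adjusted p = 4.12e-05), as had Gm4724, Gm15387 and Rpl31-ps8, which share reads with parent genes, at 0.65, 0.63 and 0.60. Of 40 postsynaptic genes 2 were more positive and 19 more negative, and 2 and 21 over the list alone. Their median was -0.15 (camera adjusted p = 8.96e-07, p = 0.356 with an estimated correlation). Nrxn2 was at -0.35 ± 0.044 and Nlgn3 at -0.17 ± 0.026. Of 21 endothelial and mural markers 0 were more positive and 10 more negative, and 1 and 14 over the list alone (median -0.31, camera adjusted p = 2.44e-05, p = 0.832 with an estimated correlation). Of 80 oxidative phosphorylation genes 31 were more positive and 7 more negative, and 34 and 9 over the list alone (median 0.12, camera adjusted p = 2.5e-06, p = 0.832 with an estimated correlation). Of 82 ribosomal protein genes 29 were more positive and 6 more negative, and 32 and 6 over the list alone. Their median was 0.11 (camera adjusted p = 3.74e-05, p = 0.832 with an estimated correlation). Ncan and Bcan, matrix proteoglycans, stood at -0.33 ± 0.034 and -0.42 ± 0.067, Atp5mpl at 0.31 ± 0.043 and Rpl22l1 at 0.43 ± 0.066.

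The interaction called 3692 genes, 1605 more positive and 2087 more negative in HT. Without the HT fluoxetine females, limma called 0 genes, with 957 at an unadjusted p under 0.05. Col1a1 then stood at -0.82, near its value with all libraries, and Gm15387 at 0.42 (adjusted p = 0.888). Hspg2, Acta2 and Vwf were at -0.28, -0.34 and -0.33 and Nrxn2 and Ncan at -0.07 and -0.10. mt-Atp6 stood at 0.04 (adjusted p = 0.984), and Gm4724 and Rpl31-ps8 turned to -0.26 and -0.11. The medians of the postsynaptic, vascular, oxidative phosphorylation and ribosomal lists were -0.02, -0.23, 0.01 and -0.04. With the GC and length trend removed 659 genes were called, and Nrxn2, Nlgn3, Rpl22l1, Gm4724 and Rpl31-ps8 lost their calls at -0.12, -0.12, 0.19, 0.43 and 0.43 (adjusted p 0.0502 to 0.205). With both slopes as covariates 216 were called, and the calls of Gm15387, Nrxn2, Nlgn3 and Ncan stood. The other 11 of 15 ended (adjusted p 0.0834 to 0.731), with Col1a1, Acta2, mt-Atp6, Bcan and Rpl31-ps8 at -0.82, -0.65, 0.60, -0.31 and 0.77 and Hspg2, Vwf, Atp5mpl, Rpl22l1 and Gm4724 at -0.38, -0.38, 0.16, 0.13 and 0.26. Naa15 stood at 0.16 ± 0.058 (adjusted p = 0.0461), and at -0.04 and -0.05 under these settings. It was not called without any 1 of HT fluoxetine female replicates 2, 3 and 4 (0.0691, 0.0698, 0.0703), HT fluoxetine male replicates 1 and 2 (0.0955, 0.0547), HT vehicle female replicates 2, 4 and 5 (0.0667, 0.0611, 0.0585), HT vehicle male replicates 1, 2 and 4 (0.0516, 0.0706, 0.0666), WT fluoxetine female replicates 1, 3 and 5 (0.0521, 0.0697, 0.0707), WT fluoxetine male replicates 2, 3, 4 and 5 (0.0593, 0.0518, 0.0677, 0.0534), WT vehicle female replicates 1 and 5 (0.0985, 0.06) and WT vehicle male replicates 3, 4 and 5 (0.072, 0.0685, 0.0516).

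The interaction of genotype with lithium called 0 genes with limma, with 1058 at an unadjusted p under 0.05; edgeR called 0 and DESeq2 2. The 10 genes with the smallest p were Gm17132, Flvcr1, a haem exporter, Tmem208, Rpl10a, a ribosomal protein gene, Ramp1, a receptor activity-modifying protein, Sertad2, Utp14b, Arid3a, Gm48362 and Gskip, an inhibitor of the kinase GSK3. Their differences were 0.91 ± 0.22, 0.22 ± 0.056, -0.20 ± 0.052, -0.26 ± 0.068, -0.25 ± 0.069, 0.20 ± 0.054, 0.49 ± 0.14, 0.27 ± 0.075, 1.41 ± 0.39 and -0.20 ± 0.055, each with an adjusted p of 0.832, and none passed. Naa15 stood at 0.001 ± 0.058. Of 80 oxidative phosphorylation genes 0 were more positive and 0 more negative (median -0.09, camera adjusted p = 8.78e-19, p = 0.817 with an estimated correlation), and of 82 ribosomal protein genes 0 were more positive and 0 more negative, and 0 and 1 over the list alone (median -0.09, camera adjusted p = 3.57e-14, p = 0.817 with an estimated correlation).

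**Figure D4:**
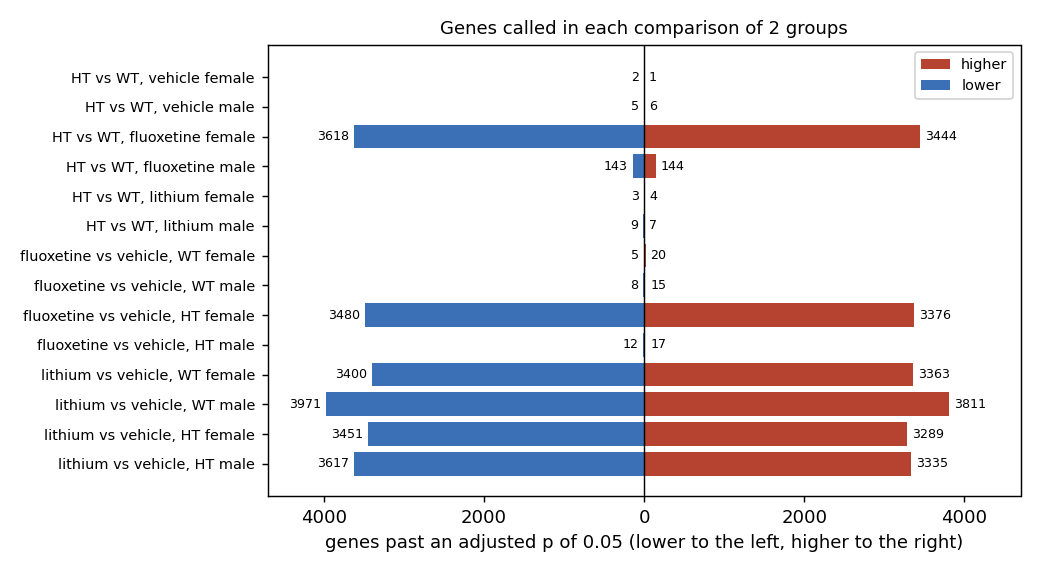
Number of genes past an adjusted p of 0.05 in each of 14 comparisons of 2 groups, higher to the right and lower to the left. Lithium called 6740 to 7782 genes in each of its 4 strata, and fluoxetine 6856 in HT females and 23 to 29 in the other 3.

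Whether females and males differ in their response to fluoxetine was tested as an interaction (female minus male). mt-Atp6 had a more positive response in females at 0.71 ± 0.15 (adjusted p = 0.00795). Adgrg1, an adhesion receptor of cortical development, Ltbp3, which binds latent TGF-beta, and Grin2d had a more negative one at -0.48 ± 0.11, -0.42 ± 0.10 and -0.39 ± 0.082 (adjusted p 0.00793 to 0.0156). Of 80 oxidative phosphorylation genes 10 were more positive and 0 more negative, and 32 and 0 over the list alone (median 0.11, camera adjusted p = 1.34e-09, p = 0.911 with an estimated correlation). Atp5mpl was at 0.25 ± 0.043 and Cox6c at 0.22 ± 0.043. Gm28438 was at 0.47 ± 0.11 and Naa15 at 0.04 ± 0.058 (adjusted p = 0.776). In all 278 genes were more positive and 215 more negative in females. Without the HT fluoxetine female libraries limma called 0 (1136 at an unadjusted p under 0.05), and mt-Atp6, Atp5mpl and Gm28438 turned to -0.11, -0.0163 and -0.07. Adgrg1, Ltbp3 and Grin2d were then at -0.19, -0.26 and -0.19, and the oxidative phosphorylation median was 0.01. The count was also 287 and 245 without HT fluoxetine female replicates 1 and 2, 276 and 256 without HT fluoxetine male replicates 4 and 5, and 256 without HT vehicle female replicate 4. It was 174, 949 and 299 without HT vehicle male replicates 1, 3 and 4, and 300 and 294 without WT fluoxetine female replicates 1 and 4. It was 266 and 325 without WT fluoxetine male replicates 2 and 5, 284 without WT vehicle female replicate 5, and 261 without WT vehicle male replicate 3. DESeq2 gave 814. With the GC and length trend removed it was 22. The 7 named calls then ended (adjusted p 0.0565 to 0.405), 5 at similar folds and Grin2d at -0.17.

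The response to lithium differed between the sexes in 2 genes. Cdh5 was at 0.49 ± 0.093 and Grm3, a metabotropic glutamate receptor, at 0.36 ± 0.071 (adjusted p = 0.0367 for both; 0.0514 for Grm3 with the GC and length trend removed), each more positive in females. Ptgdr, Ehd2, Alcam, Olfml3, Cd93, Helz2 and Coa5 were at 1.21 ± 0.25, 0.50 ± 0.10, 0.33 ± 0.071, 0.49 ± 0.11, 0.73 ± 0.16, 0.64 ± 0.14 and 0.17 ± 0.037, and 2410006H16Rik at -0.36 ± 0.075 (adjusted p 0.058 to 0.0632), and did not pass. Naa15 stood at -0.05 ± 0.058 (adjusted p = 0.726). Of 18 meningeal and fibroblast markers 0 were more positive and 0 more negative, and 17 and 0 over the list alone. Their median was 0.53 (camera adjusted p = 2.89e-14, p = 0.27 with an estimated correlation). Of 21 endothelial and mural markers 1 was more positive and 0 more negative, and 13 and 0 over the list alone (median 0.28, camera adjusted p = 4.94e-14, p = 0.27 with an estimated correlation). Of 82 ribosomal protein genes 0 were more positive and 0 more negative, and 0 and 35 over the list alone. Their median was -0.13 (camera adjusted p = 3.2e-19, p = 0.364 with an estimated correlation). Of 15 markers of the olfactory bulb and rostral stream 0 were more positive and 0 more negative, and 0 and 10 over the list alone. Their median was -1.37 (camera adjusted p = 1.48e-07, p = 0.498 with an estimated correlation). By tool, edgeR called 3 genes and DESeq2 86, and 2511 genes had an unadjusted p under 0.05.

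Single libraries decided this count of 2. It was 0 without any 1 of HT lithium female replicates 3 and 5, HT lithium male replicates 2 and 5, HT vehicle female replicates 3 and 5, and HT vehicle male replicates 1 and 4. The same held for WT lithium female replicates 2 and 5, WT lithium male replicates 1 and 3, WT vehicle female replicates 1, 3 and 5, and WT vehicle male replicates 1 and 2. It was 1 without HT lithium male replicate 3 or WT vehicle male replicate 4. It rose to 22 without HT lithium female replicate 2, 25 and 9 without HT lithium male replicates 1 and 4, 47 and 22 without HT vehicle female replicates 2 and 4, and 12 and 98 without HT vehicle male replicates 2 and 3. It rose to 5 and 4 without WT fluoxetine male replicates 3 and 5, and to 26, 6 and 21 without WT lithium female replicates 1, 3 and 4. It rose to 4, 6 and 33 without WT lithium male replicates 2, 4 and 5, 186 and 7 without WT vehicle female replicates 2 and 4, and 11 without WT vehicle male replicate 5. Cdh5 or Grm3 or both lost their calls in the runs with 0 or 1, and some of the 8 genes that did not pass were called in the runs with more.

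The difference between HT and WT itself was compared between the sexes (female minus male). mt-Atp6 was at 0.83 ± 0.12 (adjusted p = 0.000112) and Htr2a at 0.39 ± 0.10 (adjusted p = 0.0234, 0.054 without HT vehicle male replicate 3). Gm21887 and Rpl10a-ps1, which share reads with related genes, Slc32a1, the vesicular GABA transporter, and Gm13889 were at -1.71 ± 0.35, -0.58 ± 0.12, -0.55 ± 0.12 and -0.50 ± 0.11 (adjusted p 0.0098 to 0.0139). Grin2d and Jun were at -0.45 ± 0.067 and -0.33 ± 0.058. Of 82 ribosomal protein genes 0 were more positive and 10 more negative, and 1 and 30 over the list alone (median -0.10, camera adjusted p = 1.76e-12, p = 0.451 with an estimated correlation), with Rps23 at -0.40 ± 0.069. Of 80 oxidative phosphorylation genes 0 were more positive and 5 more negative, and 0 and 13 over the list alone. Their median was -0.07 (camera adjusted p = 1.1e-05, p = 0.631 with an estimated correlation), with Ndufb10 at -0.26 ± 0.057. Naa15 stood at 0.05 ± 0.047 (adjusted p = 0.657). In all 89 genes were more positive and 178 more negative in females, and limma called 0 without the HT fluoxetine female libraries (990 at an unadjusted p under 0.05). Htr2a, Rpl10a-ps1, Gm13889, Jun and Rps23 then had similar folds of 0.33, -0.51, -0.43, -0.30 and -0.33, and mt-Atp6 and Ndufb10 had 0.29 and -0.13. The 267 calls became 153 and 488 without HT fluoxetine female replicates 2 and 5, and 436 and 167 without HT fluoxetine male replicates 1 and 4. They were 159 without HT lithium female replicate 5, 175 without HT lithium male replicate 4, and 128 and 450 without HT vehicle male replicates 3 and 4. They were 166 without WT fluoxetine male replicate 3, 174 without WT lithium female replicate 4, 486 without WT lithium male replicate 1, and 403 without WT vehicle female replicate 1. They were 44 with the GC and length trend removed, where Htr2a, Gm21887, Slc32a1, Grin2d and Gm13889 lost their calls at 0.34, -1.39, -0.40, -0.21 and -0.28 (adjusted p 0.0528 to 0.33), and 526 with DESeq2. With both slopes Htr2a, Gm21887, Slc32a1, Gm13889, Jun and Ndufb10 lost theirs (0.0713 to 0.284), 5 at similar folds.

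Females were compared with males over all groups. Xist, the RNA that silences one X chromosome, was higher by 8.62 ± 0.38. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were at -9.92 ± 0.19, -8.64 ± 0.11, -9.31 ± 0.18 and -9.62 ± 0.21 (adjusted p 3.55e-51 to 6.47e-25). Of 23 markers of oligodendrocytes and myelin 5 were higher and 0 lower, and 20 and 1 over the list alone. Their median was 0.35 (camera adjusted p = 1.08e-07, p = 0.939 with an estimated correlation). In all 636 genes were higher and 931 lower in females. Hnrnpul1, an RNA-binding protein gene, Gnai2, a G protein subunit gene, Gal3st3, a sulfotransferase gene, and Cdh22, a cadherin gene, were at -0.09 ± 0.014, -0.11 ± 0.018, -0.12 ± 0.021 and -0.16 ± 0.028. Without the HT fluoxetine female libraries 20 genes were higher and 7 lower, and Hnrnpul1, Gnai2, Gal3st3 and Cdh22 (adjusted p 0.241 to 0.389) lost their calls at folds of -0.04, -0.04, -0.07 and -0.09. With the GC and length trend removed 62 and 108 were called. Naa15 stood at 0.07 ± 0.023 (adjusted p = 0.0589). It was called without any 1 of HT fluoxetine female replicate 5 (0.0319), HT fluoxetine male replicate 1 (0.0238), HT lithium male replicate 5 (0.0449), HT vehicle female replicate 2 (0.0475), HT vehicle male replicate 3 (0.0488), WT fluoxetine female replicate 5 (0.0472), WT lithium female replicate 2 (0.0295), WT lithium male replicate 2 (0.0426) and WT vehicle female replicates 2 and 4 (0.0311, 0.0471).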

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

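The tests of explanations for the 3 patterns weighed here were chosen after the results had been seen, and the random regroupings of the libraries before.

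Within single groups, 9 of 156 examined sets of replicates held a library far from the others, and chance flags about 1 in 20 groups. The mitochondrial share was 6.74% in HT vehicle female replicate 4, against 5.23% to 5.60% in the other 4. The GC slope was -0.0708 in WT vehicle female replicate 1 (others 0.102 to 0.168), and the length slope -0.0558 in HT lithium male replicate 4 (others -0.0352 to -0.0296). On the log2 scale Kif5c was at 14.54 in WT fluoxetine male replicate 5 (others 14.69 to 14.73), and Hist1h1c at 8.96 in HT fluoxetine male replicate 2 (8.63 to 8.72). Fkbp5 was at 9.77 in WT vehicle female replicate 3 (9.54 to 9.60) and Arc at 12.76 in WT fluoxetine female replicate 5 (11.30 to 11.67). Hif3a was at 8.73 in HT fluoxetine female replicate 3 (8.29 to 8.42) and at 8.45 in WT fluoxetine male replicate 1 (8.87 to 9.01). Effects differed between groups by the interaction tests in 3692 genes for genotype and fluoxetine, 493 for sex and fluoxetine, 2 for sex and lithium and 267 for sex and genotype.

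The first pattern is the breadth of the lithium change together with the place of the HT fluoxetine female libraries among the lithium libraries. Bias by GC content or length is argued against as the whole cause: after removal of each library's trend 59.7% of the 11287 lithium calls were called in the same direction, with the median signed fold going from 0.24 to 0.14, though with both slopes as covariates that median was 0.0722 (median SE 0.117) and 1603 genes were called. The HT fluoxetine female profile may reflect a feature of handling or tissue that is not lithium: across 17891 genes its change against HT vehicle females had a Pearson r of 0.676 with the lithium change in WT, against 0.188, -0.109 and 0.105 for HT males, WT females and WT males of the fluoxetine groups with the lithium change in the other genotype. A wrong label on these 5 libraries cannot be told apart from it, because over the 63 genes called for fluoxetine and not for lithium elsewhere their mean score of 0.0560 showed no rise over the 0.0724 of HT vehicle females, which goes with a wrong label, but lay 0.132 above HT lithium females (exact permutation p = 0.0397), which goes against it. The labels give no batch, so a preparation batch that follows treatment, a response of HT females to fluoxetine, and a response to lithium itself stay open and untested for the genes that moved with the profile.

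The second pattern is the interaction of genotype with fluoxetine. Of its 3692 calls 96.7% had the sign of lithium against vehicle in WT, in line with the profile of the HT fluoxetine female libraries as its source. A response of HT mice shared by both sexes stays open: in males the called genes had a median of 0.0826 in the direction of the interaction, with quartiles of 0.0375 and 0.149 and the same sign in 90.1%, against 0.35 in females, but they were called on an average that includes the males.

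The third pattern is the set of 530 HT against WT calls (Kif5c, Hist1h1c and Gm5784 among them) averaged over the 5 strata of treatment and sex other than fluoxetine females, where 431 had the averaged sign in each stratum and 19 were also called under vehicle alone. Variants linked to the targeted Naa15 locus are argued against as the cause of the set, since 94.9% of the calls lay on other chromosomes and 1 lay within 10 Mb (2.49 expected, one-sided Fisher's exact p = 0.921). Linked segments elsewhere stay open: a window of 4 Mb on chromosome 2 held 10 calls, all lower, where 6 of 1000 random placements held as many, and a segment of chromosome 12 with Gm5784 and 2410018L13Rik held 9, all lower, of 22 tested genes. For the zinc finger genes of that window, reads moved between near-identical copies could not be excluded either: over all treatments 11 were called lower and 1 higher, and the summed level of 40 genes differed by -0.0616 (permutation p = 0.0483), which goes against it, but so small a fall near the threshold does not exclude it. A biological effect of Naa15 on these genes stays open as well, and counts of Naa15 itself do not settle it.

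Random regroupings tested whether chance could give as many calls, with 100 regroupings per comparison, the real one included. Only the real grouping reached its count, so chance can be excluded, for HT against WT under vehicle (19, highest other 1) and over all treatments (2637, 305), fluoxetine (3579, 1935), lithium (11287, 3789) and lithium against fluoxetine (9638, 2864). The same held for fluoxetine in WT (182, 21) and HT (5579, 820), lithium in WT (9467, 5317) and HT (9054, 5479), genotype by fluoxetine (3692, 2784), sex by genotype (267, 81) and female against male (1567, 2). By stratum it held for HT against WT in vehicle males (11, 5), fluoxetine females (7062, 4691) and fluoxetine males (287, 8). It held for fluoxetine in WT females (25, 3) and HT females (6856, 4291), and for lithium in WT females (6763, 4312), WT males (7782, 4101), HT females (6740, 3795) and HT males (6952, 5838). For HT against WT in lithium females 2 of 100 were as large (7, 126). The same held for fluoxetine in WT males (23, 41) and HT males (29, 154). For sex by fluoxetine 3 were (493, 1299). For sex by lithium 4 were (2, 859), and leaving out single libraries gave 0 to 186. These ranks, uncorrected over the comparisons, are weak evidence against chance. Chance cannot be excluded either for HT against WT in vehicle females (3, 5 of 100 as large, highest other 541) and lithium males (16, 6 of 100, highest other 75). For genotype by lithium (0 by limma with 1058 at an unadjusted p under 0.05, edgeR 0 and DESeq2 2) any regrouping reaches the real count (100 of 100, highest other 1133), so the regroupings do not test it. Regrouping single libraries takes no account of litters, which the labels do not give, so a litter effect is not excluded in the treatment comparisons. Regroupings that called several times the real count, as in sex by lithium, sex by fluoxetine, genotype by lithium, fluoxetine in HT males and HT against WT in vehicle females, lithium females and lithium males, point to a structure of the samples, which was not examined further.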

How the results depend on the processing

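Leaving out the HT fluoxetine female libraries, the treatments of GC content and length, edgeR and DESeq2 were chosen after the data had been seen. The results were repeated under 21 settings and without each of the 59 libraries. No filter, added constants of 0.5 and 5, the robust variance prior and edgeR left every count of called genes within 1.5 times. Of 193 results for named genes, 18 crossed the threshold on leaving out at least 1 library, and the other calls kept their direction and side. The counts below are of called genes. Sex by lithium gave 0 without the intensity trend, 6 with quantile normalisation, 9 with median centring and 13 among genes with a mean of at least 100. It gave 0 in a fit of its groups alone, 0 with the replicate block and 4 with a block by library number. HT against WT under vehicle gave 7 among genes with a mean of at least 100 and 6 in a fit of its groups alone, where fewer genes and fewer residual degrees of freedom were used. With 1 residual component HT against WT under vehicle gave 53, fluoxetine in WT 380, sex by fluoxetine 1096, sex by lithium 732, sex by genotype 798 and female against male 2779. With 2 components these were 133, 692, 1812, 1397, 1650 and 3708, with 4341 for HT against WT over all treatments and 44 for genotype by lithium. DESeq2 gave 30 for HT against WT under vehicle, 2 for genotype by lithium, 814 for sex by fluoxetine, 86 for sex by lithium and 526 for sex by genotype.

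Without the HT fluoxetine female libraries the counts were 530 for HT against WT over all treatments, 372 for fluoxetine, 26 for fluoxetine in HT, 27 for female against male and 0 by limma for genotype by fluoxetine, sex by fluoxetine and sex by genotype (957, 1136 and 990 at an unadjusted p under 0.05). The r between the drugs was then 0.322, and 0.395 with all groups and divided vehicle libraries. With the GC and length trend removed they were 2225 for fluoxetine, 2775 for fluoxetine in HT, 659 for genotype by fluoxetine, 22 for sex by fluoxetine, 44 for sex by genotype, 170 for female against male and 25658 summed over the 14 comparisons by stratum (42556 in the report's fit). With the slopes as covariates they were 29 for HT against WT under vehicle, 946 for fluoxetine, 1603 for lithium, 1387 for lithium against fluoxetine, and 857 for fluoxetine in HT. They were 1394 and 1320 for lithium in WT and HT, 216 for genotype by fluoxetine, 0 by limma for sex by fluoxetine, 239 for sex by lithium, 27 for sex by genotype, 338 for female against male and 6754 by stratum. The slopes differ between the lithium and vehicle groups, so this setting also removes part of the contrast. Of 232 calls of gene lists 0 held with an estimated correlation. In its place fry called 0 for HT against WT under vehicle (camera 7) and genotype by lithium (11), 1 for sex by genotype (21) and sex by fluoxetine (8), 3 for sex by lithium (17) and female against male (9), 4 for fluoxetine in WT (12), 8 for genotype by fluoxetine (15), 28 for lithium in WT (18) and 32 for lithium (19). For the other counts above the cause was not tested.

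Gene values that changed direction were, without the HT fluoxetine female libraries, mt-Atp6 for fluoxetine (-0.14) and sex by fluoxetine (-0.11) and Gm4724 and Rpl31-ps8 for genotype by fluoxetine (-0.26 and -0.11). Atp5mpl and Gm28438 did so for sex by fluoxetine (-0.0163 and -0.0706), which was then of WT alone. Naa15 turned with the GC and length trend removed and with the slopes as covariates, to -0.13 and -0.15 for lithium, -0.11 and -0.13 for lithium against fluoxetine and -0.0410 and -0.0526 for fluoxetine in HT. It turned to -0.11 and -0.14 for lithium in WT, -0.16 and -0.17 in HT, and -0.0358 and -0.0545 for genotype by fluoxetine. With the slopes as covariates mt-Nd3 turned to -0.11 for fluoxetine and -0.96 for lithium, and for lithium Gm28438 turned to -0.00641, Gm29216 to -0.55, Htr2a to -0.23 and Htr6 to 0.16. The cause of these changes in direction was not tested.

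Leaving out single libraries gave 10 to 29 calls for HT against WT under vehicle and 2330 to 3133 over all treatments, 3256 to 3804 for fluoxetine (96 to 294 in WT, 5018 to 5712 in HT) and 11097 to 11356 for lithium (9088 to 9526 in WT, 8676 to 9161 in HT). It gave 9435 to 9720 for lithium against fluoxetine, 3213 to 4000 for genotype by fluoxetine, and 0 to 0 by limma for genotype by lithium (1058 at an unadjusted p under 0.05 with all libraries). It gave 174 to 949 for sex by fluoxetine, 0 to 186 for sex by lithium, 128 to 488 for sex by genotype, 1076 to 2118 for female against male and 40760 to 43176 by stratum. The Naa15 difference between HT and WT stayed between 0.01 and 0.03. Replicate numbers do not pair the libraries: residuals correlated by 0.0104 on average between libraries with the same number, and 16 of 59 libraries were closest to 1 with their own number. With replicate number as a block fluoxetine gave 1726 higher and 1857 lower and lithium 5849 and 5437. The scaling moved the division between directions for sex by genotype, from 89 more positive and 178 more negative to 172 and 202 with quantile normalisation and 137 and 116 with median centring, and for sex by lithium from 2 and 0 to 5 and 1, and 8 and 1. Depth limits the weakest genes, since the tested genes reach down to a normalised count of 10 in 4 libraries.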

Other observations

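Further lists of genes moved beside those described above. Of 86 genes of autism risk, which include chromatin regulators and synaptic proteins, under lithium 10 rose and 57 fell, and 10 and 58 over the list alone (median -0.18, camera adjusted p = 2.48e-07, p = 0.359 with an estimated correlation). Of 38 genes of the proteasome, which degrades tagged proteins, under lithium 24 rose and 6 fell (median 0.13, camera adjusted p = 0.0018, p = 0.669 with an estimated correlation). With the GC and length trend removed the proteasome call ended (camera adjusted p = 0.394, median 0.01) and that for autism risk genes did not (4.82e-09).

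HT vehicle female replicates 4 and 5 had levels of Arc and Hif3a like those of the drug groups. Arc was at 10.54 and 11.03 on the log2 scale in these libraries and at 12.46 to 12.99 in the other 3 of the group, and Hif3a at 8.82 and 8.56 against 6.82 to 7.81. These values were picked out after they were seen, and no explanation was tested.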
